A study of Mus musculus with 10 samples.

How the data were processed

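The samples are 10 arrays of gastrocnemius, 5 from Skn-1 knockout and 5 from wild-type male mice fasted for 18 h. Per the labels' protocols, the knockout arose on a mix of 129 and C57BL/6J, and over 10 generations of crossing to C57BL/6J followed. RNA was extracted with Trizol and a column kit, and 100 ng of total RNA was labelled with a 3' IVT kit. The deposited values are read as already normalized between arrays by the authors, because the array medians differ little; software and method are not given in the sources used here. The deposited values are taken as log2 from their range (4.93 to 13.96), and the log base is not stated anywhere, so folds rest on that reading.

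The values had an unusual spread. Over the 10 arrays, 86.2% of the 45037 probe sets had an SD at or below 0.01 (median 0.000189), and the other 6209 had a median SD of 0.168. The first kind is called low-variation here and the second ordinary. A difference of a low-variation probe set is not a fold change in RNA and is not printed as one. Its test still compares the groups with that probe set's own spread. Across ordinary probe sets the correlation between pairs of arrays ran from 0.950 to 0.993.

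The deposited table has 45101 rows, of which 64 array controls were left out of the tests. Gene names come from the platform annotation, updated through gene identifiers with a RefSeq gene table of the GRCm38.p6 assembly. Of the probe sets, 34945 had 1 gene, 932 had several and 9160 were unnamed; 34741 of the first kind matched the gene table. Each of 18193 genes was represented by its probe set with the highest mean over all arrays, called the brightest. The gene table was used only for names, chromosomes and gene order, since the array values carry no build, and no coordinates are given.

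The main tests between genotypes were fixed before the data were examined. The test of the components, the splits of the arrays for genes and probe sets, and most tests of explanations were chosen after results were seen. Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), with Benjamini-Hochberg adjustment at 0.05 over genes and, separately, over probe sets. Gene lists, 40 with 756 genes, were written before the data were examined. The 39 with at least 4 measured members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. No list passed with the estimated correlation, where 1 had an unadjusted p under 0.05. With fry, which asks whether the genes of a list move one way on balance, no list passed and 1 had an unadjusted p under 0.05. Its mixed test, for change in either direction, called 1 list, cholesterol synthesis (adjusted p = 9.83e-07), with 2 at an unadjusted p under 0.05. Single values (Pou2f3 and array quality) were compared with exact two-sided permutation tests. The genes on each side of Pou2f3, 100 by plan, were compared with all others by Fisher's exact test, because a 129 segment can remain around a targeted gene.

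Genes were named by a fixed rule. Pou2f3 came first, then up to 12 genes in each direction past the threshold without overlap between groups. Directions with fewer than 8 were filled to 8 by unadjusted p. In each list up to 4 members past the threshold were named, or otherwise up to 2 with the smallest p. Clone and predicted names were counted and not named. Low-variation list members taken by the rule are left out of the text, since their values have no size that can be read.

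The fits were tested on simulated data made from the means and residual SDs of the 18193 genes, with 100 genes changed by 0.5 and 100 by 1 (log2) for the knockout comparison. Over 10 runs limma recovered 44.2% of the first and 83.2% of the second, with 5.42% false calls, and made 0 calls in all runs where nothing was changed. A rank product test recovered 96.0% and 100.0% with 318 false calls. With equal SDs for all genes it made 4, so its assumption of a common spread does not hold for these values. A list moved by a known amount was found in 8 of 10 runs, and a moved region around Pou2f3 in 10 of 10. The simulated genes were drawn independently. The runs thus do not show the rate of false calls where genes move together, as the lymphocyte markers did (estimated correlation 0.843).

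Alternatives fixed before the data were examined covered normalization, filters on level, variance moderation, array weights, the replicate number as a block, each array left out, 2 covariates for tissue mixture, the choice of probe set per gene, other tests and other widths of the region. A pseudocount did not apply, since the values are logged. Alternatives added after seeing the data left out low-variation probe sets, arrays with genes of other tissues or the genes around Pou2f3, took the most variable probe set per gene or widened the region to 500 genes. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.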

Results

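Gene expression was measured with Affymetrix mouse genome arrays in the gastrocnemius, a calf muscle, of male mice that lacked Skn-1 and of wild-type mice. Skn-1 is another name of Pou2f3, a POU-domain transcription factor that taste and tuft cells need. All muscles were taken after 18 h of fasting, at an age of 12 to 16 weeks. There were 5 arrays of each genotype, which the labels call biological replicates. The median deposited value lay between 6.23 and 6.24 in every array, and the highest value in each array was 13.96. The number of arrays limits the precision of every comparison, and differences are given as knockout minus wild type on a scale taken as log2. The comparison asks which transcripts differ in fasted muscle when Skn-1 is missing.

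The targeted gene itself did not separate the genotypes. The single Pou2f3 probe set stood at 6.47 ± 0.00029 (SD, n = 5) in knockouts and at 6.47 ± 0.00024 (SD, n = 5) in wild types. Its difference was within the spread between arrays (exact two-sided permutation p = 0.571). The probe set belonged to the large class that hardly varied on the deposited scale, and the labels do not say which part of the gene was removed, so this value does not check the labels. Eif2s3y, a Y chromosome gene that marks males, stood at 8.72 ± 0.0887 (SD, n = 5) in knockouts and at 8.58 ± 0.198 (SD, n = 5) in wild types. Xist, which silences the second X chromosome of females, was near 5.92 in both genotypes, in a probe set that hardly varied.

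Muscle of knockout and wild-type mice differed in few genes as read from the brightest probe set of each. Of 18193 genes tested, 5 passed an adjusted p of 0.05 with limma, 3 of them higher and 2 lower in knockouts. Just 3410 of the 18193 had a brightest probe set that varied on an ordinary scale. With the most variable probe set per gene, a choice made after seeing the data, 61 passed. At an unadjusted p under 0.05 there were 987 genes where chance gives 909.65, but 263 after quantile normalization and 249 with arrays centred on the median. On the deposited scale 1.07% of genes had no overlap between the genotypes where chance gives 0.794%. The smallest p was that of Nxpe4, of the neurexophilin and PC-esterase domain family, which fell from 7.57 ± 0.130 (SD, n = 5) in wild types to 5.78 ± 0.0845 in knockouts. Wild types thus had 3.45 times the knockout level (log2 difference −1.79 ± 0.07 SE, limma adjusted p = 4.23e-05). Plet1os, a transcript from the strand opposite Plet1, fell from 7.50 ± 0.261 to 5.43 ± 0.107 (log2 difference −2.07 ± 0.12 SE, limma adjusted p = 0.000869). Wild types had 4.21 times its knockout level. For both genes the knockout level lay below the array medians of 6.23 to 6.24 and was not shown to be above background. The 2 folds are thus those of the deposited values, and the size of the change in RNA is uncertain.

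Fdx1 and Sc5d were higher in knockouts. Fdx1, the ferredoxin that passes electrons to mitochondrial cytochrome P450 enzymes, stood at 10.49 ± 0.103 (SD, n = 5) against 9.75 ± 0.118 in wild types. This was 1.67 times the wild-type level (log2 difference 0.74 ± 0.07 SE, limma adjusted p = 0.0193). Sc5d, the sterol C5-desaturase of cholesterol synthesis, stood at 7.77 ± 0.155 against 6.88 ± 0.154 (log2 difference 0.90 ± 0.10 SE, limma adjusted p = 0.0359). Its other 2 probe sets hardly varied and had the opposite sign. The fifth gene, the unnamed clone 6820431F20Rik, was named after its values were seen and differed by 0.45 ± 0.04 SE (limma adjusted p = 0.026). Nxpe4, Plet1os, Fdx1 and 6820431F20Rik each had 1 probe set, so no second probe set could check them. In each of the 5 genes all arrays of one genotype lay above all arrays of the other. Nxpe4 and Plet1os each passed under 23 of 24 alternatives, the exception being the fit without the 5 arrays that carried genes of other tissues (adjusted p = 0.725 and 0.507). Over all alternatives the log2 difference stayed between −1.83 and −1.71 for Nxpe4 and between −2.14 and −1.90 for Plet1os, so these calls ended with 5 arrays left and little change in size. Fdx1 passed in 14 of 25 (log2 difference 0.70 to 0.79), Sc5d in 11 of 25 and 6820431F20Rik in 11 of 24 (0.42 to 0.51). The Sc5d difference ran from 0.30 to 0.98 and was lowest with the mean of all its probe sets.

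**Figure D1:**
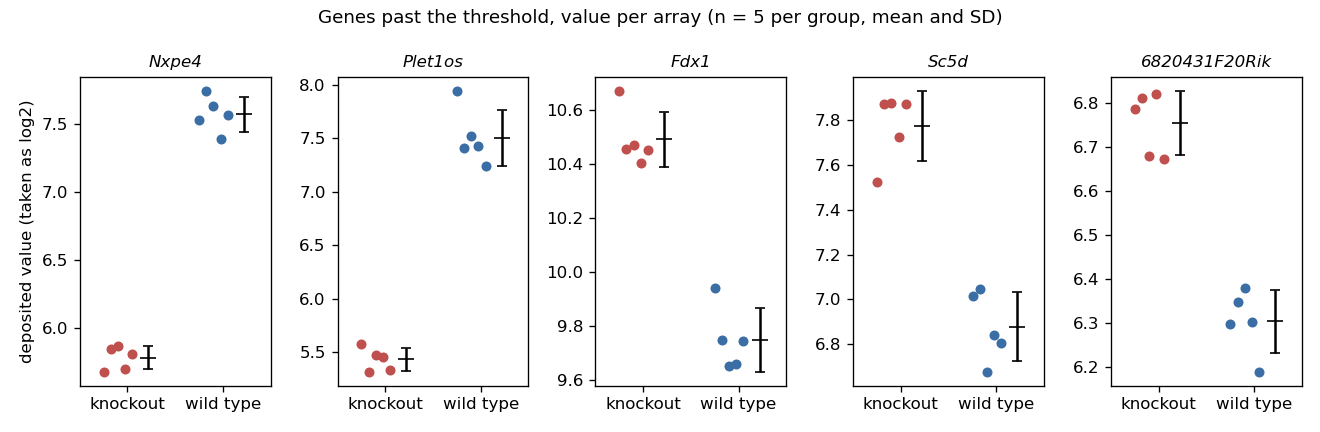
Deposited value, taken as log2, of the 5 genes that passed an adjusted p of 0.05, with 1 point per array and the mean with its SD beside the points (n = 5 per genotype); each panel has its own axis. Nxpe4 and Plet1os were lower in all knockout arrays, and Fdx1, Sc5d and 6820431F20Rik were higher, with no overlap between the genotypes.

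The genes next in line did not pass over genes, though the probe sets of some passed over single probe sets. Among lower values in knockouts were Alg9, a mannosyltransferase of N-glycan synthesis (log2 difference −0.58, limma adjusted p = 0.0668), and Sorl1, a sorting receptor (−0.68, adjusted p = 0.156). Rps25, of the small ribosomal subunit, differed by −0.39 (adjusted p = 0.156), Preb by −0.47 and the coronin Coro2b by −0.45 (both adjusted p = 0.197). On the higher side were the initiation factor Eif5b (0.27, adjusted p = 0.233), Prrc2c (0.58) and Csnk2a1, the catalytic subunit of casein kinase 2 (0.29, both adjusted p = 0.262). Of these genes, 3 had a second probe set that varied. It differed by 0.32 for Prrc2c (unadjusted p = 0.000967), by 0.08 for Csnk2a1 (unadjusted p = 0.541) and by 0.00077 for Sorl1 (unadjusted p = 0.991), so that the Sorl1 difference was not seen there. The rule also took Ppcdc, Edn3, Dnajb14 and Dpagt1, whose brightest probe sets hardly varied, so that their differences have no size to report. A dimmer probe set of Ppcdc, an enzyme of coenzyme A synthesis, did vary and was lower in knockouts (−1.10, unadjusted p = 1.07e-08), against the sign of the brightest. Over single probe sets it passed (limma adjusted p = 0.00024). The same held for the probe sets above of Alg9 (limma adjusted p = 0.0213), Rps25 (0.0385) and Sorl1 (0.0395). Those of Preb, Coro2b, Eif5b, Prrc2c and Csnk2a1 did not pass there either.

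The genes that differed lay mostly around Pou2f3 on chromosome 9. In the gene order of the reference table, Sc5d lies 13 places before Pou2f3, and Nxpe4, Plet1os and Fdx1 lie 139, 181 and 225 places after it, while 6820431F20Rik is on chromosome 8. Of the 20 genes with the smallest p, 16 lay within 500 places of Pou2f3. In the planned window of 100 genes on each side, 18 of 75 tested genes (24.0%) had an unadjusted limma p under 0.05, against 5.35% of the other 18117 (Fisher's exact test, two-sided p = 7.2e-08, odds ratio 5.59, 95% interval 3.08 to 9.68). By the adjusted threshold 1 of 75 near genes passed against 4 of the others (Fisher's exact test, two-sided p = 0.0204), and this 1 gene, Sc5d, was lost in 8 of the 10 fits that left out an array. With 200 genes on each side, 34 of 120 (28.3%) were at an unadjusted p under 0.05, and 3 passed the adjusted threshold.

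Across the genome no other stretch came near this density. At an unadjusted p under 0.01 chromosome 9 held 53 of 1002 genes (5.29%), and the next, chromosome 16, held 12 of 592 (2.03%). A window of 50 consecutive tested genes held at most 16 such genes on chromosome 9, from Cep164 to Alg9, and at most 5 elsewhere, on chromosome 3. Within 500 places of Pou2f3, 29 genes that varied on an ordinary scale reached p under 0.01, 10 of them higher and 19 lower in knockouts. Among these were Srpr, the receptor for the signal recognition particle (log2 difference 0.50), Nnmt, nicotinamide N-methyltransferase (−1.15), Slc37a4, the glucose 6-phosphate transporter (0.58), and Dlat, a subunit of pyruvate dehydrogenase (0.33). None of these 4, chosen after their values were seen, passed the adjusted threshold.

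**Figure D2:**
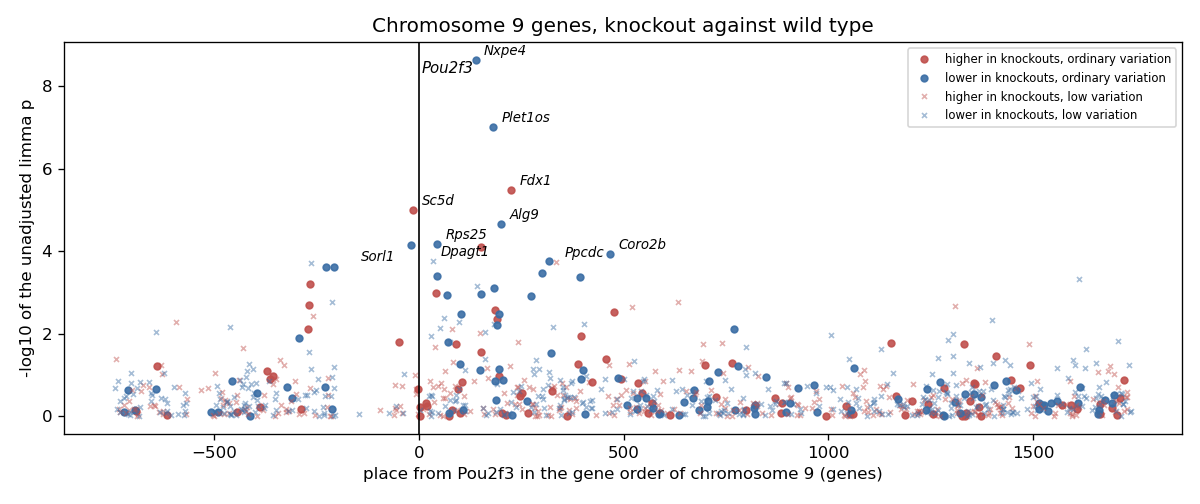
Each point is a gene of chromosome 9, placed along the horizontal axis by its number of places from Pou2f3 in the reference gene order, with −log10 of the unadjusted limma p on the vertical axis; filled circles vary on an ordinary scale and crosses hardly vary. Genes with small p gather from about 300 places before to 500 places after Pou2f3, where Nxpe4, Plet1os, Fdx1 and Sc5d lie.

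Over single probe sets the picture was wider, and mostly higher in knockouts. Of 45037 probe sets, 86 passed an adjusted limma p of 0.05, 70 of them higher and 16 lower. Of the 86, 60 varied on an ordinary scale, and for the rest the difference has no size that can be read. Of the 73 with 1 gene, 15 from 14 genes lay within 500 places of Pou2f3, among them Atm, the DNA damage kinase (log2 difference −0.44, adjusted p = 0.0069), and Ddx6, an RNA helicase (0.50, adjusted p = 0.00496). The other 58 lay elsewhere. Among them were 40 ordinary-varying probe sets that were not the brightest of their gene, and all 40 were higher in knockouts. The dimmer probe set of Jam2, a junctional adhesion molecule of vessels, was at 2.44 times the wild-type level (limma adjusted p = 0.0019), that of the ubiquitin ligase Nedd4 at 1.87 times (adjusted p = 0.00226), that of the kinase Jak1 at 1.57 times (adjusted p = 0.00641) and that of the acetyltransferase Crebbp at 1.55 times (adjusted p = 0.00393). In wild types those of Jam2 (6.13) and Crebbp (5.94) lay below the array medians and were not shown to be above background. The size of these 2 folds is thus uncertain, while Nedd4 (9.52) and Jak1 (7.56) lay above the medians. A dimmer probe set of Adipor2, an adiponectin receptor, was at 1.44 times the wild-type level (adjusted p = 0.0301). That of Myoz1, a Z-disc protein of fast fibres, was at 1.58 times (adjusted p = 0.0352). These 8 genes were chosen after their values were seen.

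The brightest probe sets of the same genes were not chosen for passing, so the sizes cannot be set against those of the called ones. Those of Myoz1 (log2 difference −0.06) and Adipor2 (−0.0063) had the opposite sign, that of Jam2 hardly varied, and those of Nedd4 (0.16), Crebbp (0.16) and Jak1 (0.21) were slightly higher, with unadjusted p from 0.0523 to 0.0991. In 22 of these genes the brightest probe set also varied, and 16 of these probe sets were higher in knockouts. Over all ordinary-varying probe sets outside the region around Pou2f3, whatever their p, 14.3% of the 2001 that were not the brightest were higher in knockouts at an unadjusted p under 0.05 and 2.00% were lower. Among the 3324 brightest probe sets these shares were 3.46% and 2.32%. With the most variable probe set taken for each gene, a choice made after seeing the data, 61 genes passed, 52 of them higher, and with the mean of all probe sets of a gene 29 passed. The count of 86 fell to between 31 and 57 in the fits without 1 array, and to 5 with the replicate number as a block. It fell to 4 without the 3 arrays that carried lymphoid or hair genes. Without the 5 arrays that carried genes of any other tissue it was 0 (limma, 2672 at an unadjusted p under 0.05), where fewer arrays also leave less power.

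**Figure D3:**
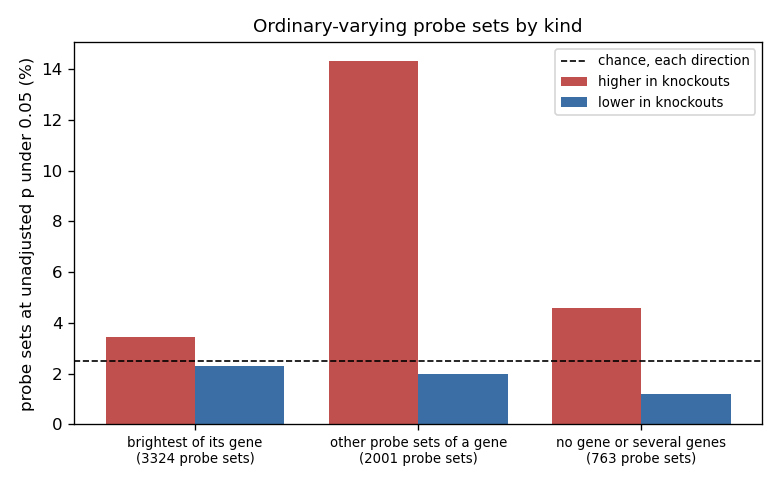
Share of ordinary-varying probe sets outside the region around Pou2f3 with an unadjusted limma p under 0.05, in percent, split by direction (bars) and by kind of probe set; the dashed line is the 2.5% that chance gives in each direction. Probe sets other than the brightest of a gene were higher in knockouts in 14.3% of cases, against 3.46% for the brightest.

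No gene list of fuel use in the fasted muscle passed with camera on the deposited scale, and this depended on the scaling. After quantile normalization 8 of these 9 lists passed, and with arrays centred on the median 7 did, all higher in knockouts. Over all 39 lists each of these scalings called 23. They also left 263 and 249 genes at an unadjusted limma p under 0.05, where chance gives 909.65. Before centring, the array medians ran from 6.226 in wild type 4 to 6.239 in wild type 3. That range is far wider than the median SD of low-variation probe sets (0.000189). Centring thus moved most genes together by more than their own spread, and quantile normalization also turned low-variation genes such as Ppcdc. Camera ranks a list against the other genes, so these passes cannot be told from that shift and do not show a rise of fuel use. In the fits without 1 array up to 4 of the 9 passed, all higher. With slow fibre genes as a covariate 3 passed as higher and the respiratory chain as lower, and without the 5 arrays that carried genes of other tissues fatty acid oxidation alone of the 9 passed, as lower (adjusted p = 0.00462). On the deposited scale, of 26 measured genes of fatty acid oxidation and ketone use none passed, 17 were higher and 9 lower, and the list did not pass (camera adjusted p = 0.191). Of the 17 that varied on an ordinary scale 11 were higher. Bdh1, of ketone body use, differed by −0.24 and Hadh by 0.11. The respiratory chain, with 41 genes, was split 20 higher to 21 lower (adjusted p = 0.981), with Ndufa2 at −0.11. Among its 24 genes that varied on an ordinary scale 13 were higher. The tricarboxylic acid cycle (adjusted p = 0.175) held Dlat, which lies near Pou2f3, at 0.33 and Sdhd at −0.10. Glycolysis, with Hk2 at 0.17 and Pgam2 at 0.09, gave an adjusted p of 0.455. For glucose uptake and glycogen it was 0.0865, with Tbc1d1 at 0.19, and for glucose sparing in fasting 0.263, with Foxo1 at 0.24 and Nr1d1 at 0.20. Lipid uptake and droplets (0.117, Dgat2 at 0.13) and fatty acid and triglyceride synthesis (0.488, Gpam at 0.21 and Elovl6 at 0.20) did not pass either. In cholesterol synthesis Sc5d alone of 17 genes passed, and the list did not pass by camera (adjusted p = 0.26). The mixed test of fry, for change in either direction, did call this list (adjusted p = 9.83e-07). Just 4 of its 17 genes varied on an ordinary scale, 2 higher and 2 lower. Sc5d, which lies near Pou2f3, alone passed when adjusted over the list. The fry test was not run without Sc5d, so the call does not show a change of the pathway.

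Among lists of heat production, hormone response and fibre type, the first alone passed on the deposited scale, and just with the preset correlation. Of 20 genes of uncoupling and heat production 14 were higher in knockouts, as were 9 of the 12 that varied on an ordinary scale. The list passed as higher by camera with the preset correlation (adjusted p = 0.0387). With an estimated correlation its adjusted p = 0.796 (unadjusted p = 0.0243). The list passed in 17 of 27 alternatives and was lost without knockout 4 (adjusted p = 0.0753), knockout 5 (0.0827) or wild type 3 (0.0924), 3 arrays that carried genes of other tissues. Its mean deviation was highest in knockout 4 (0.27), which carried epidermis genes, and lowest in knockout 1 (−0.14), which carried them too. Its leading member, Ppargc1a, the coactivator that drives mitochondrial biogenesis, stood at 8.59 ± 0.801 (SD, n = 5) in knockouts and 7.60 ± 0.203 in wild types, and did not pass (adjusted p = 0.832). It was highest in knockout 4, at 9.78, and at 7.61 in knockout 1. The mitochondrial biogenesis regulators, which also hold Ppargc1a, did not pass as a list (adjusted p = 0.191), with Opa1 at 0.14. Adrenergic and cAMP-responsive genes had an adjusted p of 0.0857, with Nr4a1 at 0.72 and Myf6 at 0.20, and immediate early genes 0.069, with Egr1 at 8.61 in knockouts and 7.61 in wild types. Slow and oxidative fibre genes (0.0857, Csrp3 at −0.35, Ankrd2 at −0.30) and fast fibre genes (0.156, Mybpc2 at 0.07) did not pass. The clock (0.24, Nfil3 at 0.48), glucocorticoid response (0.175, Zbtb16 at 0.48, Nr3c1 at 0.14) and insulin and IGF signalling (0.49, Irs2 at 0.36, Igfbp5 at 0.14) did not either.

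Ribosomal protein, matrix, interferon and nerve genes shifted only by the test with a preset correlation. Among 21 ribosomal protein genes that varied on an ordinary scale 20 were lower in knockouts. Of all 26 measured, 25 were lower (camera adjusted p = 0.000693, and adjusted p = 0.796 with an estimated correlation). The direction turned without knockout 5 and wild types 1 and 3, which carried lymphoid or hair genes (adjusted p = 0.962), and the list's mean deviation was highest in wild types 1 (0.18) and 3 (0.13). None passed over all genes, and Rps25, which lies 45 places from Pou2f3, passed when adjusted over the list alone (adjusted p = 0.00171). Of 25 matrix and fibroblast genes 20 were higher (adjusted p = 0.00394), with Lum at 0.30 and Mmp2 at 0.17. Among the 21 that varied on an ordinary scale 16 were higher. Of 22 interferon-stimulated genes 19 were higher (adjusted p = 0.0107), with Igtp at 0.49 and Rsad2 at 0.24, and lymphocyte genes were high in the same array, knockout replicate 5, without which the adjusted p was 0.615. All 14 interferon genes that varied on an ordinary scale were higher. Of 14 nerve and Schwann cell genes 13 were higher (adjusted p = 0.0387), but just 6 varied on an ordinary scale, all 6 higher. This list passed in 11 of 27 alternatives and in 4 of the 10 fits without 1 array, where the matrix list passed in 8, the interferon list in 7 and the ribosomal proteins in 9. It was lost with array weights (adjusted p = 0.165) and among genes above the median level (adjusted p = 0.124). With an estimated correlation each of the matrix, interferon and nerve lists had an adjusted p = 0.796. Without wild type replicate 1, which carried hair genes, none of the 5 lists that shifted passed (adjusted p = 0.0983 for each).

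The remaining lists did not pass on the deposited scale. Protein breakdown and autophagy had a camera adjusted p of 0.28 (Map1lc3a at −0.10), branched-chain amino acid breakdown 0.488 (Hsd17b10 at −0.12), heat shock and chaperones 0.0857 (Cryab at −0.19, Dnajb4 at −0.16) and the amino acid and endoplasmic reticulum response 0.508 (Atf4 at −0.12). Oxidative stress genes gave 0.24, with Gclc at −0.29 and Gpx4 at −0.14, the cell cycle 0.639, with Pcna at −0.06, and satellite cell genes 0.488. Denervation and junction genes gave 0.28 (Hdac4 at 0.23) and myokines 0.738. Other POU family members, relatives of the targeted gene, gave 0.175, and taste and tuft cell markers 0.738. In these lists 1 of 10 and 3 of 17 genes varied on an ordinary scale. The sex-linked genes gave 0.49. The median and mean of the ordinary-varying members and the direction of the test differed in sign for cholesterol synthesis, satellite cell, denervation, adipocyte, respiratory chain and red blood cell genes. Across all 39 lists tested, 681 genes were measured, and 1 of them (Sc5d) passed over all genes, while 2 (Sc5d and Rps25) passed when adjusted over the list alone.

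Genes of other tissues stood out in single arrays. B-cell and T-cell genes were high in knockout replicate 5 and wild type replicate 3: Cd79b stood at 8.38 and 8.28 there, and between 5.41 and 5.62 in the other 8 arrays. As a list the lymphocyte markers did not pass (camera adjusted p = 0.765), nor did macrophage (0.191), red blood cell (0.88, with 7 of 8 genes that hardly varied), endothelial (0.143, Emcn at −0.20) or adipocyte markers (0.738, Lep at 0.33 and Orm1 at 0.17). Hair genes, in a list drawn up after the data were seen, were high in wild type replicates 1 and 3, where the hair follicle gene Tchh stood at 9.72 and 8.58 against 5.16 to 5.35 elsewhere. Epidermis genes were high in knockout replicates 1 and 4, where Krt10 stood at 8.90 and 9.17, and at 6.68 to 7.82 in the others. No wild type had a median deviation of epidermis genes above 0.45. Without knockout 5 and wild types 1 and 3, 2 genes passed (limma), and without knockouts 1 and 4 as well 0 passed, with 936 at an unadjusted p under 0.05.

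**Figure D4:**
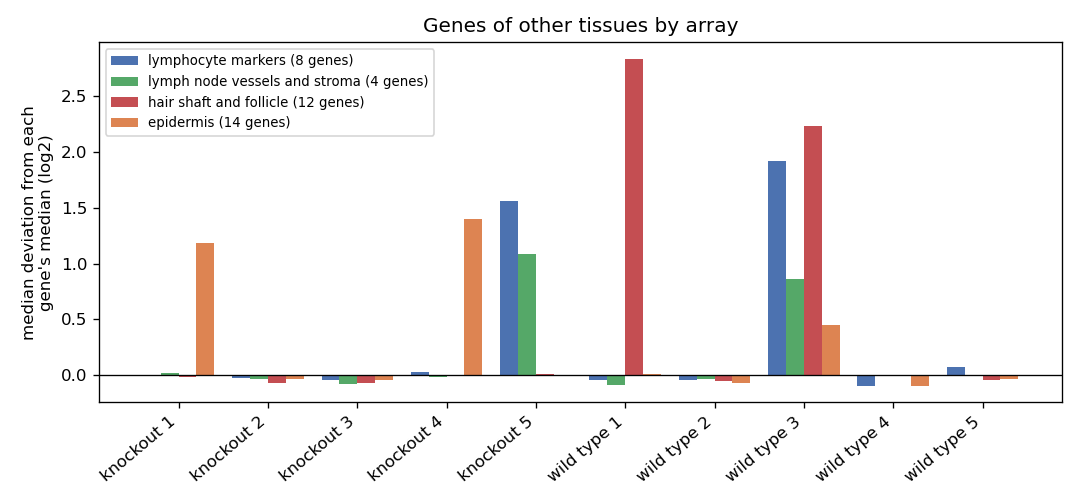
For each array, the median over a marker list's ordinary-varying genes of each gene's deviation from its own median over the 10 arrays (taken as log2), with 1 bar per list. Lymphocyte genes rise by 1.57 in knockout 5 and 1.92 in wild type 3, hair genes by 2.84 in wild type 1 and 2.23 in wild type 3, and epidermis genes by 1.19 in knockout 1 and 1.41 in knockout 4.

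Measures of array quality did not separate the genotypes. The difference between the 3' and 5' control probe sets of Gapdh was 0.413 ± 0.088 (SD, n = 5) in knockouts and 0.413 ± 0.0696 in wild types (exact two-sided permutation p = 0.992). For Actb it was 0.619 ± 0.193 against 0.526 ± 0.147 (exact two-sided permutation p = 0.397). Over all 14 measures, which include spike-in and 18S ribosomal RNA controls, the lowest exact permutation p was 0.175 and the lowest adjusted value 0.586, where 5 against 5 arrays can reach 0.00794. The 18S controls varied between single arrays: the 3' probe set was highest in wild type 1 (11.14), knockout 4 (11.06) and knockout 1 (10.86), and stood at 9.29 to 10.60 in the others. Wild type 3, which carried hair genes as wild type 1 did, was at 9.47.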

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

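Chosen after the result was seen were the tests of loss acting anywhere, of mismatches with 129 sequence, of blood, of dim probe sets, of whole-gene change and of handling, and the splits for genes and probe sets.

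The genes that differed clustered around Pou2f3, with 24.0% of near genes at an unadjusted p under 0.05. Of 100 splits of the arrays 1, the real grouping, gave as high a share, with 14.7% the highest of the others, so chance is argued against. Loss of Pou2f3 acting on genes with no regard to place does not by itself give the cluster, since the odds were 5.59 times those of other genes in the planned window (95% interval 3.08 to 9.68); the 10.6 times for 500 genes on each side at an unadjusted p under 0.01 restates the cluster, and effects on single genes stay open. Mismatches with 129 sequence that only lower the signal of probes are argued against as the whole cause, since 34.5% of the 29 ordinary-varying segment genes at an unadjusted p under 0.01 were higher in knockouts (17.9 to 54.3). A fault of a single probe set per gene cannot be told apart, since only 5 other probe sets varied and 60% of them had the same sign (14.7 to 94.7). A candidate explanation is a 129 segment carried along with the targeted gene, which needs genotypes to test; local effects of the altered gene on its neighbours also stay open.

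Genes of other tissues were high in single arrays of both genotypes, and blood left in the muscle is argued against for knockout 5 and wild type 3. The test planned for it was void, since 7 of 8 red cell markers hardly varied, but 4 probe sets shared by adult globin genes did vary. In these 2 arrays their log2 difference from the median of the other 8 was −0.353 to −0.0626, at most 0.39 with 2 SD of those added, where the median rise of the lymphocyte genes over the same arrays was 1.64 in knockout 5 and 1.94 in wild type 3 (single genes 0.49 to 2.88). Lymph node tissue in the dissected muscle may account for these arrays: all 4 varying genes of a lymph node list (Cr2, Fcer2a, Ccr7 and Cd37) had them highest, with Ccr7 at 6.97 and 6.98, but lymphocytes also express these genes. For wild type 1, skin and hair tissue in the dissected muscle was predicted to make it the highest array of the epidermis genes; it was for 0 of 14, but this bound was wrong, because knockouts 1 and 4 carried epidermis genes (median deviations 1.19 and 1.41). Skin thus cannot be told apart there: the epidermis median was 0.01, Krt14 stood at 6.98 and Perp at 7.52, and hair genes, listed after they were seen in this array, were highest in 12 of 12. RNA breakdown there stays open: the 3' to 5' differences were not the highest (0.452 for Gapdh and 0.46 for Actb), but the 18S ribosomal RNA signal was the highest of 10 for the 3' probe set (11.14) and next to the highest for the 5' one (12.07), and no biological explanation was tested.

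Probe sets other than the brightest of a gene were higher in knockouts. The splits counted all called probe sets, whatever their kind, place or direction. Of 100 splits 1, the real grouping, called as many as the 86 found, with 2 the highest of the others. Chance is thus argued against for that count, but the splits did not test this pattern by itself. Dimness of the probe sets other than the brightest is argued against as the whole cause. At matched level their odds of being higher were 4.72 times those of the brightest (95% interval 3.73 to 5.96). A change of the whole gene is argued against as the whole cause, since over 1004 genes, taken whatever their p, the higher one was the next brightest in 76.7% of the 116 genes where just 1 of the 2 brightest was higher at an unadjusted p under 0.05 (68.0 to 84.1), while in 29 genes both were. Groups handled apart before or during labelling cannot be told apart, since no batch is given and the lowest adjusted p of the quality measures was 0.586. A difference of the transcripts' ends or unspliced RNA between genotypes was not tested and stays open.

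For the count of 5 genes, 2 of the 100 splits, drawn from 126 possible, gave as many. They were the real grouping and a mixed one, knockouts 1 and 2 with wild types 1, 3 and 5, which called 10. That share lies under the 5% limit of this test, which was chosen after the count was seen. A grouping apart from genotype called more genes than genotype did, so chance is not excluded for this count. For the 5 gene lists, 90 of 100 splits gave as many, with 19 the highest of the others, so chance is not excluded.

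In 10 of 212 groups of 5 arrays, 1 array stood far from the rest, where chance gives about 5%. Fdx1 was at 10.67 in knockout replicate 1, and at 10.41 to 10.47 in the other knockouts. Rps25 was at 7.24 in the same array, and at 7.04 to 7.09 in the others. Nr1d1 stood at 7.23 in wild type replicate 1, against 6.78 to 6.89. Igtp stood at 9.24 in knockout replicate 5, against 7.26 to 7.53. As mean deviations over a list, interferon-stimulated genes were at 0.998 in knockout replicate 5, and lymphocyte markers at 1.30 there and at 1.45 in wild type replicate 3. Mitochondrial biogenesis regulators were at −0.30 in wild type replicate 5, and nerve and Schwann cell markers at 0.25 there and at −0.25 in knockout replicate 4.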

How the results depend on the processing

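The alternatives chosen after seeing the data left out low-variation probe sets, arrays with genes of other tissues or the region around Pou2f3, took the most variable probe set per gene or widened the region to 500 genes. Over 24 or 25 alternatives each, the 5 genes kept their direction, and 82 of 122 values stayed past the threshold. The share of near genes at an unadjusted p under 0.05 stayed above that of the others in every alternative run, from 12.0% with centred arrays to 42.1% among varying probe sets. Pou2f3 and array quality kept their side of the threshold, and a pseudocount was not run. Signal over background limits dim genes, and the cause of each change below was not tested unless given.

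Quantile normalization called 43 probe sets and 23 lists, and turned Ppcdc (−0.0027), Edn3 (−0.0059) and Dnajb14 (−0.0019). Median centring called 23 lists and turned Ppcdc (−0.000301) and Dnajb14 (−0.00024); these genes hardly varied. Above the median level 3 lists passed; among the brightest class 2 genes and 33 probe sets did. With the replicate number as a block, 3 genes, 0 near Pou2f3, 5 probe sets and 8 lists passed. Whether the numbers pair the arrays is not settled. Same-number correlations ran from −0.44 to 0.33, and 2 of 5 knockout arrays were closest to the wild type of their own number. With adipocyte markers as a covariate 0 near genes passed. With slow fibre genes as a covariate 3 genes, 0 near, 24 probe sets and 11 lists did, and Pgam2 was −0.022; of the 5 lists 2 were kept, and heat production (adjusted p = 0.0533), matrix (0.0591) and nerve (0.279) were lost. The mean of all probe sets per gene gave 29 genes, 3 near, 8 lists and Ppcdc at −0.36. Without probe sets ending in x or s, Edn3 (−6.25e-05) and Coro2b (0.000153) turned, because another probe set stood in. Rank product called 397 genes, 9 near, which cannot be read since its equal-spread assumption failed on simulated data. A plain two-sample test called 0 near genes, and an estimated correlation 0 lists, with 1 at an unadjusted p under 0.05.

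Among varying probe sets alone 14 genes, 3 near, and 143 probe sets passed, with fewer tested. Without knockout 5 and wild types 1 and 3, 2 genes, 0 near, 4 probe sets and 2 lists passed; Foxo1 (−0.0078), Ndufa2 (0.014) and the ribosomal proteins (adjusted p = 0.962, with 0.0983 or less in each fit without 1 array) turned. Without knockouts 1 and 4 as well, 0 genes (limma, 936 at an unadjusted p under 0.05), 0 near, 0 probe sets and 9 lists passed, and Gpx4 was 0.0071. Without the genes within 500 places of Pou2f3, 0 genes passed (limma, 925 at an unadjusted p under 0.05). The most variable probe set gave 61 genes, 4 near, and Ppcdc at −1.10. With 200 and 500 genes on each side, 3 and 4 near genes passed.

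Leaving out each array in turn gave 2 to 5 genes, 0 to 1 near, 31 to 57 probe sets and 2 to 12 lists. Genes fell to 2 without knockouts 2, 3 or 4 or wild types 2 to 5. The near share ran from 22.7% to 28.0%, Pou2f3 from −0.000161 to 1.13e-05, with the sign turned without knockout 2, and the lowest adjusted quality p from 0.321 to 0.937.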

Other observations

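The test of the components was chosen after the data were seen, and no explanation is offered. The first 3 principal components of the ordinary-varying genes held 31.8%, 24.97% and 15.3% of the variance. The first was highest in wild type 3 and knockout 5 (18.5 and 12.7), where lymphocyte genes were high, and the second in wild type 1 (18.7), where hair genes were high. The third separated the genotypes (exact two-sided permutation p = 0.00794, the smallest that 5 against 5 arrays can give, not adjusted for the 3 components). The separation was narrow, with the lowest knockout, 3, at −1.93 and the highest wild type, 3, at −1.99. The third component was highest in knockouts 4 and 1 (12.6 and 8.73), where epidermis genes were high.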
